A study of Bos taurus with 6 samples.

How the data were processed

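RNA-seq libraries (KAPA mRNA HyperPrep, from Trizol-extracted RNA, per the labels' protocols) were made from 6 cultures of bovine deep zone articular chondrocytes carrying doxycycline-inducible CREB5, 3 without doxycycline (Dox-) and 3 with it (Dox+). Sample titles gave both the group and the number. Per the labels' protocols, the cells had been selected with G418 at 500 µg/ml for 11 days and were cultured for 3 days in medium with 10% FBS, TGFb2 and TGFa. The labels' treatment protocol gives doxycycline as 1 µg/ml, and another text of the series gives the same number in other units, so the dose is stated only as far as that protocol goes. The p-values rest on 3 libraries per group from 3 independently collected knees, per the labels.

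The deposited table of gene signal holds normalized counts of 27607 Ensembl genes, made by the authors by dividing each library's counts by 1 size factor. FastQC 0.11.3, MultiQC 1.2, STAR 2.5.2b, Salmon and DESeq2, and the builds ARS-UCD1.2 and bosTau9, are named without role or order, per the submitters' processing notes. The annotation version and the strand setting of the counting are not given in the sources used here, so antisense or overlapping genes cannot be told apart by their reads. The authors' deposited comparison table holds a mean normalized signal, a log2 fold change with its standard error, and an unadjusted and an adjusted p-value per gene. Its mean signal equalled the mean of the 6 normalized counts within a relative difference of 7.1e-10. Whether its log2 fold changes were shrunken is not given in the sources used here, but some are too small for their p-values.

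Values of each library were whole multiples of 1 step, so the reads behind them were recovered; 100% of values above 0 came out whole within 0.01 read. Depth ranged from 20063379 reads (Dox+ 3) to 122366790 (Dox+ 2). No pair of libraries within a group differed by as little as sampling noise, with a chi-square per degree of freedom between 57.9 and 435, so each was counted as 1 replicate. FN1 held the largest share of the counts in each library, between 7.23% and 10.4%. Intervals and floors (3 reads) cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group had 0 reads, the fold was set against the mean of the floors of 3 reads in each library of the group and called a lower bound, and with 1 to 3 reads the ratio of pooled reads was given with its 95% exact interval.

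The unit of the main table is a normalized count, so the main test was limma (3.58.1, R 4.3.3; lmFit and eBayes with trend, two-sided) on log2(normalized count + 1) of the 6 libraries with group as the only term, in the 13180 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists with at least 3 tested members, and again with the correlation estimated per list and with fry, whose directional p asks whether a list's genes move one way on balance without comparing them with other genes. Of 30 lists, 22 were pathways or gene families and 8 were markers of cell types. The lists were superficial zone, joint development regulators, cartilage matrix, chondrogenic transcription factors, hypertrophy and mineralization, fibroblastic matrix, tendon and ligament, hyaluronan and lubrication, matrix proteases and inhibitors, cAMP and CREB targets, AP-1 and ATF family, TGF-beta response, BMP signalling, EGFR and MAPK feedback, Wnt signalling, inflammatory genes, interferon response, cell cycle, hypoxia and glycolysis, integrated stress and unfolded protein response, cholesterol synthesis and mitochondrially encoded genes, and, for cell types, endothelial, leukocyte and macrophage, smooth muscle and pericyte, skeletal muscle, adipocyte, osteoblast and osteocyte, synovial fibroblast and erythroid markers. Some genes stand in more than 1 list, such as PRG4, ERG, CD44, BMP6, TNC, THBS4, DPT and THY1, so results of those lists are not independent.

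The main test, its alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule named CREB5, PRG4, COL2A1, ACAN, SOX9, COL10A1 and COL1A1 whatever their result, the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean of at least 50 and no overlap between the groups, and up to 4 members of each list with the smallest p. Of the last, those not given here were counted among the members that did not pass. Symbols were taken from the authors' table, which gives one to 20730 of the 27607 genes, with 124 symbols on more than 1 identifier. RefSeq's gene table of ARS-UCD2.0, another build than the files use, was matched for 12223 of the 13180 tested genes. Its coordinates were used only for the order of genes along the chromosomes, for leaving out overlapping neighbours and for the distances between genes.

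Whether the numbers pair the libraries was decided by a rule set beforehand, a correlation over 0.1 in every pair, but the correlations and the numbers of calls with and without the block were seen at the same time. Deviations from the group means of same-numbered libraries correlated, across genes, at 0.65, 0.44 and 0.21 for numbers 1, 2 and 3, and those of other pairs at -0.59 to 0.18. Each same-numbered pair was thus above 0.1, and the numbers were taken as pairing the libraries; this rests on the data and on the 3 knees in the labels, which do not tie a number to a knee in words. The first principal component held 51.1% of the variance and the second 21.9%.

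Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, the replicate number as a block, TMM factors, quantile normalization, library weights, eBayes without trend, edgeR's quasi-likelihood test (4.0.16) and DESeq2 (1.42.0) on the recovered reads, each library left out in turn, and the block with each pair left out. The edgeR and DESeq2 fits with the block, and the list tests by estimated correlation and fry with the block, were added after the data had been seen. DESeq2 on all recovered reads with the number and doxycycline in the model gave 769 higher and 301 lower genes, the numbers of the authors' deposited table, at a filter setting of 0.1, and p-values within 0.00017 of its own, while without the number it gave 585 and 147. The table's design is not given in the sources used here.

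Each fit was tested on simulated data with the real means and library sizes, 13180 genes and 200 genes changed by known folds. In the simulation of 3 Dox+ against 3 Dox- libraries without differences between knees, limma without the block recovered 6% of genes changed 1.5-fold, 36% of those changed 2-fold, 94% at 4-fold and 100% at 8-fold, and 7.09% of its calls were false, against 8.46% in limma with the block, 8.40% and 8.33% in edgeR and 17.3% and 13.4% in DESeq2, without and with the block. With differences between knees of the size seen in the data it recovered 0%, 2%, 72% and 84%, and with the block 8%, 36%, 96% and 98%, and the false calls without and with the block were 0% and 0.833% in limma, 0% and 0.813% in edgeR and 0.885% and 5.52% in DESeq2. None of the 28 random lists was called in either simulation. Genes were drawn independently there, so this does not test lists whose genes vary together. The estimated correlation was 0.43 in the cartilage matrix list and 0.60 in the EGFR and MAPK list. No library was left out of the main comparison.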

Results

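Messenger RNA was sequenced from bovine deep zone articular chondrocytes, the cells of the cartilage layer nearest to the bone, that carried a lentiviral, doxycycline-inducible copy of bovine CREB5, a transcription factor of the CREB and ATF family. After selection in G418, the cells were kept in low attachment plates for 3 days with TGFb2 at 20 ng/ml and TGFa at 100 ng/ml, either without doxycycline (Dox-, 3 libraries) or with it at 1 µg/ml (Dox+, 3 libraries). The cells came from 3 independently collected knees, and both groups were numbered 1 to 3. The deposited normalized counts corresponded to 83206236, 40045666 and 87470127 reads in Dox- 1, 2 and 3 and to 30355805, 122366790 and 20063379 reads in Dox+ 1, 2 and 3. A floor of 3 reads was worth 1.84, 4.44 and 1.83 normalized counts in the Dox- libraries and 5.08, 1.32 and 6.98 in the Dox+ libraries, and covers counting error only. Reads were detected for between 14783 genes (Dox- 2) and 16260 genes (Dox+ 2). Values are given as normalized counts, mean ± SD with n = 3. Fold changes are differences of group means on the scale of log2(normalized count + 1). They can therefore lie above or below the ratio of the printed means, while the added 1 shrinks the change of genes with few counts.

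The comparison of Dox+ with Dox- cells asked which genes forced expression of CREB5 alters in deep zone chondrocytes. The induced gene itself, CREB5 (ENSBTAG00000018909), rose 47.8-fold, from 382 ± 111 to 18437 ± 5242 normalized counts (n = 3). Its level was 510, 308 and 330 in Dox- 1, 2 and 3 and 20935, 12413 and 21964 in Dox+ 1, 2 and 3, so each library stood on the side its label gives. PRG4 (ENSBTAG00000011932), which encodes the joint lubricant lubricin and marks superficial zone chondrocytes, rose 384-fold, from 1069 ± 580 to 392771 ± 159074 (n = 3). Between 0.493% and 1.05% of all normalized counts in the Dox+ libraries belonged to PRG4, against 0.00112% to 0.00288% in the Dox- libraries. In limma the log2 fold change was 5.58 (SE 0.28, adjusted p = 2.7e-05) for CREB5 and 8.59 (SE 0.41, adjusted p = 2.1e-05) for PRG4, and both were higher in 3 of 3 same-numbered pairs. Counts of CREB5 cannot separate transcripts of the transgene from those of the cell's own gene.

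Of 13180 genes tested, limma called 332 higher and 47 lower in Dox+ cells at an adjusted p under 0.05 (1395 at an unadjusted p under 0.05), and 328 of the higher and 46 of the lower genes were protein-coding. Several of the largest rises were in genes with almost no reads in Dox- cells. TGM3, a transglutaminase best known from the epidermis, had 1 read over the 3 Dox- libraries and 5633 ± 1385 normalized counts in Dox+ cells (n = 3), a ratio of 18830 with a 95% counting interval of 3379 to 743792. No Dox- read was counted for PLPPR4, a phospholipid phosphatase-related membrane protein, or for CALCB, a calcitonin gene-related peptide, which were at least 1134-fold and at least 422-fold higher over a floor of 3 reads in each Dox- library. FILIP1, which binds filamin, had 1 Dox- read (ratio 2460, interval 441 to 97214), and MAL2, a protein of membrane traffic, had 2 (ratio 907, interval 251 to 7494). NRG1, a growth factor that binds ERBB receptors, was listed under 2 identifiers: ENSBTAG00000004150 had 4 Dox- reads and rose 925-fold, and ENSBTAG00000054057 had 0 and was at least 284-fold higher. The division of reads between the 2 identifiers is uncertain. PI15, a peptidase inhibitor, rose 567-fold and KIF1A, a kinesin of axonal transport, rose 517-fold. With PRG4, these were the 10 largest rises among genes with a mean of at least 50. Their limma adjusted p ranged from 1.7e-06 (TGM3) to 0.00052 (KIF1A), and none of these calls was lost under any alternative run.

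With the replicate number as a block, limma called 640 genes higher and 218 lower, so 74.6% of the calls were higher, against 87.6% without the block. All 379 calls made without the block were among those made with it. Without the block, the count changed with single libraries: 138 genes were higher and 9 lower without Dox+ 3, 209 and 21 without Dox+ 1, 238 and 18 without Dox- 2, 240 and 22 without Dox- 3, and 364 and 72 without Dox- 1. These fits ignore the pairing by number. With the block and 1 pair left out, 576 to 961 genes were higher and 186 to 538 lower. Such fits leave 1 residual degree of freedom per gene. Their p-values therefore rest mostly on variance borrowed from other genes and are a weak check of single calls. Mitochondrially encoded genes held 2.04%, 1.71% and 2.20% of the counts in Dox- 1, 2 and 3 and 2.31%, 3.20% and 2.69% in Dox+ 1, 2 and 3.

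**Figure D1:**
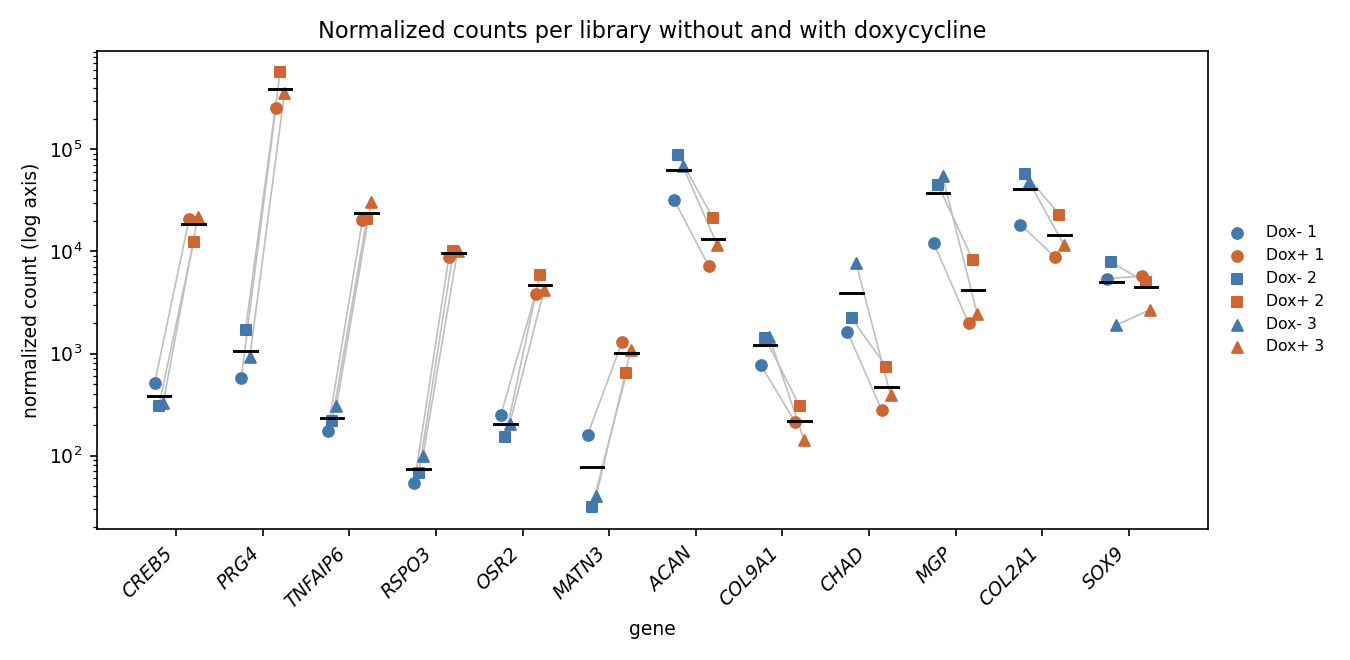
Normalized counts (log axis) of 12 genes in each of the 6 libraries; blue marks Dox-, orange Dox+, the marker shape the replicate number, grey lines join same-numbered libraries and black bars are group means (n = 3). PRG4 lay between 571 and 1705 in Dox- cells and between 253217 and 565979 in Dox+ cells, while SOX9 overlapped between the groups.

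As a list, genes of the cartilage matrix were lower in Dox+ cells (camera adjusted p = 9.9e-08, and adjusted p = 0.32 with an estimated correlation), with 3 of 16 tested members past the limma test and lower. ACAN, which encodes the main cartilage proteoglycan aggrecan, fell from 62558 ± 28201 to 13260 ± 7107 normalized counts (n = 3), a 4.78-fold fall (limma adjusted p = 0.034, and 2.4e-28 to 0.17 over 22 alternatives). COL9A1, a chain of type IX collagen, fell 5.60-fold (limma adjusted p = 0.0066), and CHAD, the collagen-binding protein chondroadherin, fell 7.05-fold (adjusted p = 0.034). MATN3, a matrilin of the cartilage matrix, went the other way and rose 16.2-fold, from 76.7 ± 71.2 to 1006 ± 337 (limma adjusted p = 0.0068). COL2A1, the type II collagen of hyaline cartilage, was 41283 ± 20422 in Dox- and 14474 ± 7515 in Dox+ cells, 2.78-fold lower in the fit and lower in each of the 3 same-numbered pairs, and did not pass (limma adjusted p = 0.22, and 0.0023 with the block).

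Of the 16 tested genes of the cartilage matrix list, 1 rose, 3 fell and 12 did not pass. When adjusted over the list alone, 1 was higher and 9 were lower, and with the block 1 was higher and 8 were lower. The median log2 fold change of the list was -1.53. Averaged over the list and centred over the libraries, the level was -0.10, 0.95 and 1.06 in Dox- 1, 2 and 3 and -1.03, 0.0069 and -0.89 in Dox+ 1, 2 and 3, so Dox- 1 lay below Dox+ 2. Without Dox- 3 the median was -1.001, and with the block and without both libraries numbered 3 it was -0.96. Markers of synovial fibroblasts moved the same way, with a median of -0.81 over 5 tested genes (camera adjusted p = 0.0070, and adjusted p = 0.25 with an estimated correlation). In limma with 1 library left out, the adjusted p of ACAN was 0.12 without Dox- 2, 0.14 without Dox- 3, 0.10 without Dox+ 1 and 0.17 without Dox+ 3, that of CHAD was 0.069 without Dox- 2, 0.11 without Dox+ 1 and 0.18 without Dox+ 3, and that of MATN3 was 0.061 without Dox+ 3.

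The 10 largest falls among genes with a mean of at least 50 also held MGP, which encodes matrix Gla protein, an inhibitor of mineralization. It fell 9.04-fold, from 37262 ± 22416 to 4220 ± 3472 normalized counts (n = 3, limma adjusted p = 0.036). GFAP, an intermediate filament protein best known from astrocytes, fell 25.0-fold (adjusted p = 0.014), and FAT2, a large cadherin, fell 10.3-fold (adjusted p = 0.040). The others were C1QL1, a secreted C1q-like protein (7.13-fold), the potassium channel gene KCNA6 (5.96-fold), INHBE, an inhibin beta subunit (4.42-fold), and NGEF (4.41-fold), with limma adjusted p between 0.011 and 0.034. Of these 10 falls, which include ACAN, CHAD and COL9A1, only that of COL9A1 kept its call with each library left out in turn. Those fits ignore the pairing by number. With the block and all libraries, the 10 falls had limma adjusted p from 6.1e-05 (ACAN) to 0.0045 (INHBE). Each of these genes was lower in every same-numbered pair.

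In limma with 1 library left out, the adjusted p of MGP was 0.14 without Dox- 2, 0.15 without Dox- 3, 0.12 without Dox+ 1 and 0.21 without Dox+ 3, and that of GFAP was 0.060 without Dox- 2 and 0.058 without Dox- 3. For FAT2 it was 0.075 without Dox- 1, 0.058 without Dox- 2, 0.17 without Dox- 3, 0.078 without Dox+ 1 and 0.060 without Dox+ 3, and for C1QL1 it was 0.082 without Dox- 2, 0.083 without Dox- 3, 0.063 without Dox+ 1 and 0.12 without Dox+ 3. INHBE had 0.13 without Dox- 2, 0.14 without Dox- 3, 0.12 without Dox+ 1 and 0.17 without Dox+ 3, NGEF had 0.069, 0.065, 0.051 and 0.066 without the same libraries, and KCNA6 had 0.060 without Dox- 3 and 0.067 without Dox+ 3. Among the 47 named genes that were called, 25 lost the call with at least 1 library left out without the block, and 0 lost it with the block and 1 pair left out. The latter fits leave 1 residual degree of freedom per gene. They called 762, 1235 and 1449 genes without pair 1, 2 and 3, against 858 with all pairs. A call kept there is thus weak evidence that it is robust.

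Among 12 tested genes of hyaluronan metabolism and joint lubrication, 3 rose, PRG4, TNFAIP6 and VCAN, and 0 fell. TNFAIP6, which encodes the hyaluronan-binding protein TSG-6, rose 102-fold, from 232 ± 65.3 to 23696 ± 5647 normalized counts (n = 3, limma adjusted p = 4.2e-06), and VCAN, the hyaluronan-binding proteoglycan versican, rose 9.68-fold, from 3164 ± 2184 to 24987 ± 2424. The other 9 did not pass. With p adjusted over the list alone, 5 were higher, among them CD44, the hyaluronan receptor, at 1.79-fold. The median log2 fold change was 0.76, with a camera adjusted p of 2.3e-05 and an adjusted p of 0.21 with an estimated correlation. Fry, which tests the list by itself, gave an adjusted p of 0.0030. The limma adjusted p of VCAN was 0.0092, and 0.063 without Dox+ 3.

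The superficial zone list did not pass as a whole. PRG4, SEMA3A (7.78-fold, limma adjusted p = 0.0058), a secreted guidance factor, and TNXB (12.5-fold), a matrix tenascin, rose among its 14 tested members and 0 fell. By p adjusted over the list alone, 4 were higher and 2 were lower, and with the block 6 were higher and 3 were lower. Among the lower ones were ERG, a transcription factor of articular chondrocytes, at 2077 ± 427 and 936 ± 291 (n = 3, limma adjusted p = 0.065, and 0.0042 with the block), and the tenascin gene TNC, 2.26-fold lower (adjusted p = 0.11, and 0.012 with the block). The list's median was 0.34 (camera adjusted p = 0.20, and adjusted p = 0.62 with an estimated correlation, 0.58 with the block). It passed in camera without Dox+ 3 (adjusted p = 0.046), with the block and without both libraries numbered 1, 2 or 3 (adjusted p = 1.4e-05, 0.00025 and 4.8e-09), and by fry with the block (adjusted p = 0.039). With the block and all libraries it did not pass in camera (adjusted p = 0.19). The fits without a pair leave 1 residual degree of freedom per gene, so their smaller p-values are no firmer evidence. For TNXB the adjusted p was 0.015, and 0.057 without Dox- 3 and 0.058 without Dox+ 3.

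Among regulators of joint development, OSR2, an odd-skipped zinc finger factor of the forming joint, rose 23.0-fold, from 202 ± 49.5 to 4667 ± 1115 (n = 3, limma adjusted p = 4.3e-05), and SOX11 rose 8.76-fold (adjusted p = 0.0034). The other 14 tested members did not pass. On a count adjusted over the list alone, 4 were higher and 1 was lower, and with the block 4 were higher and 2 were lower. The list did not pass as a whole (median 0.16, camera adjusted p = 0.16, and adjusted p = 0.62 with an estimated correlation, 0.58 with the block). It passed in camera without Dox+ 3 (adjusted p = 0.048) and, with the block, without both libraries numbered 1 (adjusted p = 0.047) or 3 (adjusted p = 0.0017). With the block and all libraries it did not pass in camera (adjusted p = 0.25).

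No chondrogenic transcription factor of the 9 tested passed. SOX9, the main regulator of the chondrocyte fate, was 5040 ± 2982 in Dox- and 4465 ± 1582 in Dox+ cells (n = 3, log2 fold change -0.02, SE 0.50, limma adjusted p = 0.99), and its sign turned with single libraries: 0.15 without Dox- 1, 0.41 without Dox- 2 and 0.31 without Dox+ 3. When adjusted over the list alone, 1 gene was higher, the homeobox gene NKX3-2 (3.33-fold, adjusted p = 0.097, and 0.0067 with the block). With the block 1 was higher and 1 was lower, the latter SOX6, a partner of SOX9 (1.84-fold lower, adjusted p = 0.46, and 0.030 with the block). At an unadjusted limma p under 0.05, 2 members passed, edgeR called 0 and DESeq2 1, and with the block both called 2. The list's median was -0.13 and its mean 0.05 (camera adjusted p = 0.81).

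In the list of hypertrophy and mineralization, BMP6, a bone morphogenetic protein, rose 70.7-fold, from 17.1 ± 7.05 to 1252 ± 380 (n = 3, limma adjusted p = 9.3e-05), and MEF2C, a transcription factor of hypertrophic chondrocytes, rose 4.37-fold (adjusted p = 0.010, and 0.083 without Dox+ 3). The other 10 tested members did not pass. With p adjusted over the list alone, 2 were higher and 4 were lower, as with the block. The lower ones included the parathyroid hormone receptor gene PTH1R (2.36-fold, adjusted p = 0.096, and 0.018 with the block) and ANKH, a pyrophosphate transporter (1.88-fold, adjusted p = 0.16, and 0.0083 with the block). COL10A1, the collagen of hypertrophic cartilage, stood below the filter for testing, with normalized counts of 0 in each Dox- library and 5.08, 4.41 and 6.98 in Dox+ 1, 2 and 3, of which the first and last equalled the floor. As a whole the list did not pass (median -0.29, mean 0.24, camera adjusted p = 0.64).

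Of secreted modulators of Wnt signalling, the R-spondins RSPO3 and RSPO2, which amplify Wnt signals, rose 134-fold and 176-fold. RSPO3 went from 73.7 ± 23.1 to 9729 ± 724 normalized counts and RSPO2 from 1.23 ± 1.62 to 370 ± 206 (n = 3, limma adjusted p = 3.1e-06 and 0.00061). The other 17 of 19 tested members did not pass. By p adjusted over the list alone, 4 were higher, and with the block 4 were higher and 1 was lower. The Wnt antagonist gene FRZB was 5.46-fold higher (adjusted p = 0.063, and 0.019 with the block). The list passed in camera (median 0.36, adjusted p = 0.0060) with an adjusted p of 0.25 with an estimated correlation, and fry gave an adjusted p of 0.0027. Its median was 0.61 without Dox- 1, 0.57 without Dox+ 2 and 0.67 with the block and without both libraries numbered 2.

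In the BMP list, the ligands BMP6 and BMP2 (1.96-fold) rose and CHRD, which encodes the BMP antagonist chordin, fell from 706 ± 134 to 248 ± 31.3 (2.82-fold, n = 3, limma adjusted p = 0.013). The other 15 of 18 tested members did not pass. On a count adjusted over the list alone, 4 were higher and 1 was lower, as with the block. The list passed in camera (median 0.70, adjusted p = 0.0062) with an adjusted p of 0.25 with an estimated correlation, and fry gave 0.020. Without Dox+ 2 the camera adjusted p was 0.064, and without Dox- 3 the median was 0.46. The limma adjusted p of BMP2 was 0.040, and it was 0.15 without Dox- 2, 0.12 without Dox- 3, 0.12 without Dox+ 1, 0.073 without Dox+ 2 and 0.23 without Dox+ 3. That of CHRD was 0.069 without Dox- 2, 0.052 without Dox- 3 and 0.089 without Dox+ 3.

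In the TGF-beta list, LTBP1, which binds latent TGF-beta in the matrix, rose 5.61-fold, from 7323 ± 2227 to 41037 ± 12872 (n = 3, limma adjusted p = 0.0024). It was the 1 call among 16 tested members, overall and adjusted over the list alone. With the block 1 was higher and 2 were lower, among them PMEPA1, an inhibitor of TGF-beta signals (2.07-fold lower, adjusted p = 0.14, and 0.022 with the block). Taken whole, the list did not pass (median -0.11, mean 0.05, camera adjusted p = 0.73).

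Feedback genes of EGF receptor and MAP kinase signalling were higher as a list (camera adjusted p = 2.3e-05, and adjusted p = 0.49 with an estimated correlation), with 2 of 18 tested members past the limma test. SPRY2, a feedback inhibitor of receptor tyrosine kinases, rose 5.04-fold, from 642 ± 291 to 3078 ± 576, and DUSP6, a phosphatase of ERK, rose 5.93-fold, from 619 ± 475 to 3227 ± 1130 (n = 3, limma adjusted p = 0.0051 and 0.025). The other 16 of 18 tested members did not pass. When adjusted over the list alone, 4 were higher and 0 lower, as with the block; the added genes were SPRY1 (4.28-fold, adjusted p = 0.060, and 0.0083 with the block) and HBEGF, an EGF receptor ligand (3.93-fold, adjusted p = 0.075, and 0.0070 with the block). The median was 0.66, and 1.01 without Dox- 1, and in the list's centred mean Dox- 1 (0.16) lay above Dox+ 2 (-0.10). For DUSP6 the adjusted p was 0.095 without Dox- 2, 0.10 without Dox- 3, 0.092 without Dox+ 1 and 0.15 without Dox+ 3.

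Among matrix proteases and their inhibitors, MMP3, the protease stromelysin-1, rose 32.8-fold, from 613 ± 723 to 15528 ± 12665, and PLAU, the urokinase that activates plasminogen, rose 2.42-fold, from 2962 ± 694 to 7153 ± 1653 (n = 3, limma adjusted p = 0.011 and 0.024). The other 14 of 16 tested members did not pass. With p adjusted over the list alone, 4 were higher and 0 lower, and with the block 5 were higher, among them the metalloproteases ADAM12 (2.44-fold, adjusted p = 0.057, and 0.0026 with the block) and ADAMTS1 (3.06-fold, adjusted p = 0.18, and 0.0067 with the block). The median was 0.35 (camera adjusted p = 0.016, and adjusted p = 0.49 with an estimated correlation), 0.57 without Dox- 1, and 0.22 with the block and without both libraries numbered 2. Averaged over the list and centred over the libraries, Dox- 1 (0.35) lay above Dox+ 2 (0.029) and Dox+ 3 (0.30). This list lost its call without Dox- 2 (0.090), Dox- 3 (0.070) or Dox+ 1 (0.056). For MMP3 the adjusted p was 0.0503 without Dox- 3 and 0.067 without Dox+ 3, and that of PLAU was 0.089 without Dox- 2, 0.075 without Dox- 3, 0.056 without Dox+ 2 and 0.14 without Dox+ 3.

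Of known targets of cAMP and CREB, PPARGC1A, a transcriptional coactivator of mitochondrial genes, rose 8.99-fold, from 21.8 ± 19.0 to 173 ± 69.3 (n = 3, limma adjusted p = 0.029). It was the 1 call among 15 tested members, also adjusted over the list alone, and with the block 5 were higher, among them RGS2, a regulator of G protein signals (12.0-fold, adjusted p = 0.22, and 0.0026 with the block). The median was 0.56 (camera adjusted p = 0.016, and adjusted p = 0.27 with an estimated correlation). It did not pass without Dox- 3 (median 0.26, adjusted p = 0.088) or Dox+ 2 (median 0.34, adjusted p = 0.052). The adjusted p of PPARGC1A was 0.089 without Dox- 2, 0.11 without Dox- 3, 0.051 without Dox+ 1, 0.081 without Dox+ 2 and 0.19 without Dox+ 3.

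No member of the AP-1 and ATF family passed among 15 tested, overall or adjusted over the list alone, and with the block 1 was higher, ATF3 (1.97-fold, limma adjusted p = 0.42, and 0.019 with the block), and 1 lower, JUN (1.83-fold, adjusted p = 0.32, and 0.048 with the block). At an unadjusted limma p under 0.05, 3 members passed, edgeR and DESeq2 called 0, and with the block they called 1 and 2. Camera did not call the list (median 0.09, camera adjusted p = 0.81).

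In the fibroblastic matrix list, POSTN, the matrix protein periostin, rose 4.68-fold, from 23111 ± 15717 to 95919 ± 24803, and FBN1, the microfibril protein fibrillin-1, rose 3.06-fold, from 59319 ± 24139 to 175282 ± 36816 (n = 3, limma adjusted p = 0.024 and 0.030). COL1A1, the type I collagen of bone and tendon, was 586416 ± 113733 in Dox- and 331886 ± 87870 in Dox+ cells, 1.79-fold lower in limma (adjusted p = 0.37, and 0.15 with the block), and DESeq2 called it lower (adjusted p = 0.045, and 0.0037 with the block). The other members did not pass either, so 2 of 16 rose and 0 fell. By p adjusted over the list alone, 5 were higher and 4 were lower, and with the block 4 were higher and 3 were lower, among them DPT, the matrix protein dermatopontin (3.99-fold higher, adjusted p = 0.072, and 0.0014 with the block). In camera the list did not pass (median -0.35, mean 0.09, camera adjusted p = 0.69). The adjusted p of POSTN was 0.11 without Dox- 3, 0.064 without Dox+ 1, 0.069 without Dox+ 2 and 0.095 without Dox+ 3, and that of FBN1 was 0.12 without Dox- 2, 0.14 without Dox- 3, 0.11 without Dox+ 1 and 0.15 without Dox+ 3.

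Of 9 tested tendon and ligament genes, 0 passed in limma, 5 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2 (4 and 6 with the block). On a count adjusted over the list alone, DPT was higher and TNC lower, and with the block 2 were higher and 2 were lower. As a whole the list did not pass (median -0.37, mean 0.0045, camera adjusted p = 0.79).

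Among inflammatory genes, the chemokine gene CXCL5 rose 45.2-fold, from 14.8 ± 14.2 to 417 ± 260, and PTGES, which makes prostaglandin E2, fell 2.95-fold, from 13825 ± 5984 to 4472 ± 808 (n = 3, limma adjusted p = 0.041 and 0.024). The other 13 of 15 tested members did not pass. When adjusted over the list alone, 1 was higher and 2 were lower, and with the block 1 was higher and 4 were lower, among them the cytokine gene IL6 (4.15-fold lower, adjusted p = 0.097, and 0.00071 with the block). Taken whole, the list did not pass (median -0.02, mean 0.30, camera adjusted p = 0.81). The adjusted p of CXCL5 was 0.067 without Dox- 2, 0.14 without Dox+ 1, 0.054 without Dox+ 2 and 0.20 without Dox+ 3, and that of PTGES was 0.059 without Dox- 2, 0.058 without Dox+ 1 and 0.15 without Dox+ 3.

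Genes of the interferon response were higher as a list in Dox+ cells (camera adjusted p = 0.00011, and adjusted p = 0.49 with an estimated correlation), but unevenly between libraries. IFI6, an interferon-induced membrane protein, rose 5.04-fold, from 294 ± 118 to 1512 ± 723 (n = 3, limma adjusted p = 0.012), and was the 1 call among 16 tested members, also adjusted over the list alone. The mean of the list, centred over the libraries, was -0.73, -0.40 and -0.94 in Dox- 1, 2 and 3 and 0.64, -0.55 and 1.98 in Dox+ 1, 2 and 3. The median log2 fold change was 1.30, and it was 0.43 without Dox+ 3, 2.24 without Dox+ 2 and, with the block, 2.31 without both libraries numbered 2. With the block and without both libraries numbered 3, the median was 0.23 and the list did not pass (adjusted p = 0.14). CD74, which leukocytes express and interferon induces, was at 63.2, 50.3 and 56.9 normalized counts in Dox- 1, 2 and 3 and at 897, 248 and 400 in Dox+ 1, 2 and 3, and rose 7.78-fold (limma adjusted p = 0.0093, and 0.063 without Dox+ 3). The adjusted p of IFI6 was 0.053 without Dox- 3 and 0.063 without Dox+ 3.

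Of 13 tested mitochondrially encoded genes, 0 passed, also adjusted over the list alone, while the list as a whole was higher (median 0.62, camera adjusted p = 0.00070, and adjusted p = 0.32 with an estimated correlation). ND2, a subunit of respiratory complex I, was 39330 ± 6499 in Dox- and 60390 ± 9484 in Dox+ cells (n = 3, limma adjusted p = 0.28). At an unadjusted limma p under 0.05, 5 passed, and edgeR and DESeq2 called 0, while with the block limma and edgeR called 0 and DESeq2 called ND2 (adjusted p = 0.036) and ND6 (adjusted p = 0.028). ND6 also passed in limma with the block without both libraries numbered 2 (adjusted p = 3.4e-05) or 3 (adjusted p = 0.045). In the same fits ATP8 passed without both libraries numbered 1, 2 or 3 (adjusted p = 4.9e-11, 1.1e-14 and 0.00019), and CYTB passed without those numbered 3 (adjusted p = 0.0012). The log2 fold change of ATP8 was 2.28, 2.17 and 0.74 there. With all libraries it was 1.73 and ATP8 did not pass (limma adjusted p = 0.35). The fits without a pair leave 1 residual degree of freedom per gene, so these calls are weak evidence. Overlapping pairs among these genes, such as ATP8 and ATP6, cannot be told apart by reads in the overlap. With the block and without both libraries numbered 2, the median was 0.34 and the list did not pass (adjusted p = 0.056).

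Genes of hypoxia and glycolysis were lower as a list (median -0.44, camera adjusted p = 0.00095, and adjusted p = 0.49 with an estimated correlation), with 0 of 16 past the limma test, 2 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2 (1 and 3 with the block). With p adjusted over the list alone, 1 was lower, the oxygen-sensing hydroxylase gene EGLN3 (3.24-fold, limma adjusted p = 0.071, and 0.0012 with the block), and with the block 2 were lower. With the block and without both libraries numbered 2, the list had an adjusted p of 0.19. In its centred mean Dox+ 1 (0.14) lay above Dox- 3 (-0.060) and below Dox- 1 (0.19). The list of the integrated stress and unfolded protein response was lower too (median -0.37, camera adjusted p = 0.011, and adjusted p = 0.62 with an estimated correlation), with 0 of 19 past the limma test, 1 at an unadjusted p under 0.05, 0 in edgeR and 1 in DESeq2 (1 in each with the block). By p adjusted over the list alone, 1 was lower, ATF5, a factor of the stress response (2.37-fold, limma adjusted p = 0.063, and 0.0026 with the block). This list did not pass without Dox- 2 (median -0.21, adjusted p = 0.17), Dox+ 1 (median -0.17, adjusted p = 0.10), or, with the block, without both libraries numbered 1 (adjusted p = 0.12). Its median was -0.57 without Dox+ 2 and -0.20 without Dox+ 3, and in its centred mean Dox+ 2 (0.22) lay above Dox- 1 (0.19) and Dox- 3 (-0.16).

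Of 21 cell cycle genes, 0 passed in limma, also adjusted over the list alone and with the block, and 0 in edgeR and DESeq2, with 1 at an unadjusted p under 0.05 (median -0.09, camera adjusted p = 0.30); among them, the replication gene MCM5 was 1.53-fold lower (limma adjusted p = 0.44). Of 16 genes of cholesterol synthesis, 0 passed in any of these ways, with 1 at an unadjusted p under 0.05 (median 0.15, camera adjusted p = 0.79), and HMGCS1, an early enzyme of the pathway, was 1.45-fold lower (limma adjusted p = 0.31). Of the 12 lists past the test with the preset correlation, 0 passed with an estimated correlation. The estimate lay below the preset 0.01 in the hyaluronan (-0.031), Wnt (-0.046), BMP (-0.022), synovial fibroblast (-0.12) and cAMP (0.0034) lists. Genes that vary together therefore do not account for the loss in these lists, and its cause was not tested. The rest of the 12 had estimates from 0.17 (mitochondrially encoded) to 0.60 (EGFR and MAPK). Fry, which compares no list with other genes, passed 4, the lists of hyaluronan, Wnt, BMP and synovial fibroblast genes, and with the block it passed the first 3 of these and the superficial zone list.

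**Figure D2:**
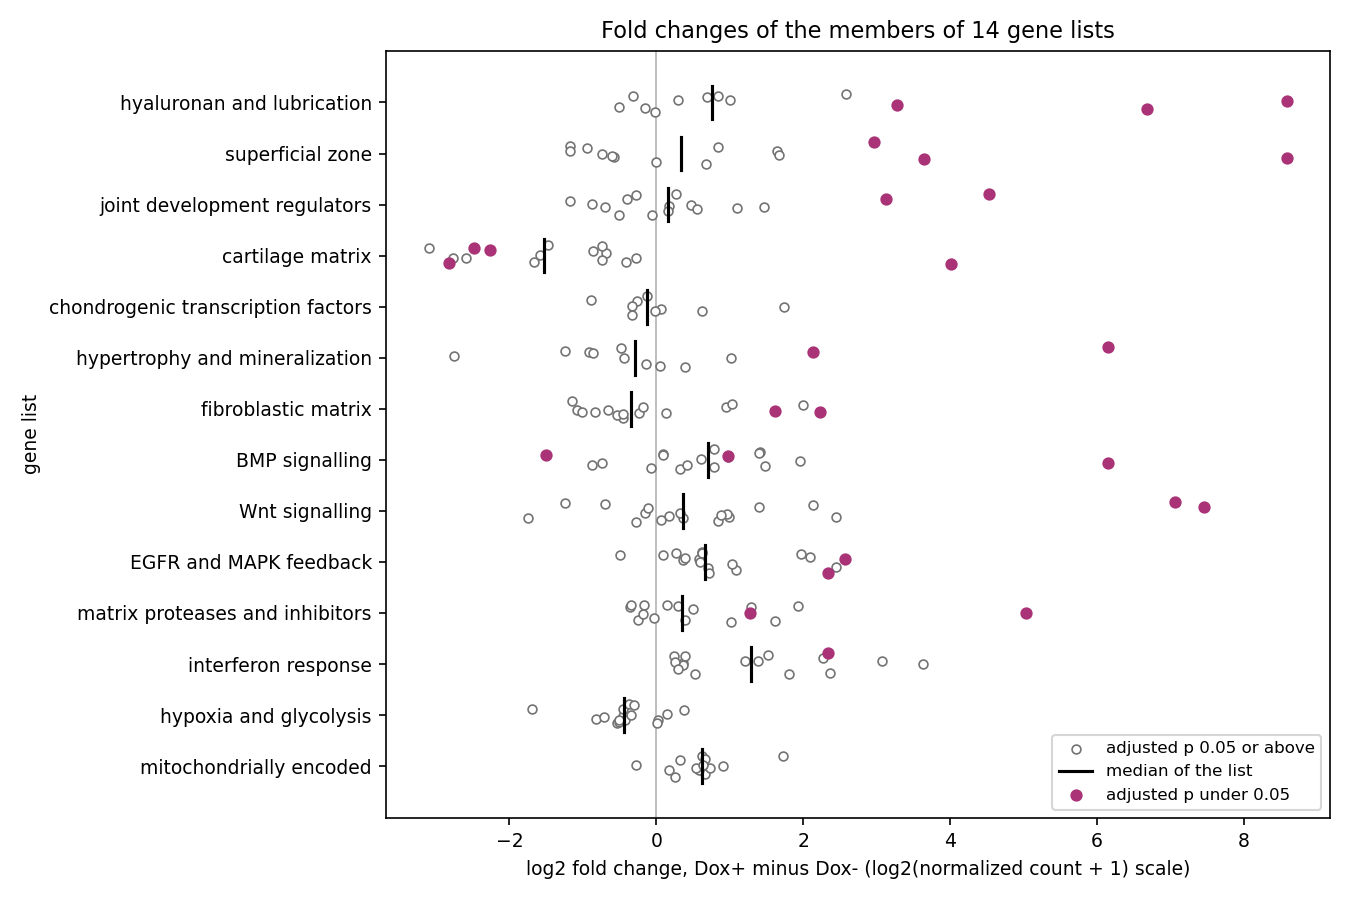
Log2 fold changes, Dox+ minus Dox-, of the tested members of 14 gene lists on the scale of log2(normalized count + 1); filled points had a limma adjusted p under 0.05 and black bars are list medians. The median was -1.53 for the cartilage matrix list and 0.76 for the hyaluronan and lubrication list.

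Markers of other cell types gave no common direction. Synovial fibroblast markers were lower as a list (camera adjusted p = 0.0070, and adjusted p = 0.25 with an estimated correlation), with 0 of 5 past the limma test, 3 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2 (2 and 3 with the block). On a count adjusted over the list alone, 2 were lower, THY1 (2.22-fold, limma adjusted p = 0.15, and 0.0049 with the block) and PDPN (1.58-fold, adjusted p = 0.15), both surface proteins of fibroblasts, and with the block THY1 and FAP (adjusted p = 0.015) were lower. The list's median was -1.23 without Dox- 1, and with the block and without both libraries numbered 2 its camera adjusted p was 0.056. By fry its adjusted p was 0.033, and 0.056 with the block. Among smooth muscle and pericyte markers MCAM, an adhesion protein, rose 41.9-fold, from 8.26 ± 0.528 to 408 ± 172, and ACTA2, smooth muscle actin, fell 4.18-fold, from 1475 ± 404 to 348 ± 65.0 (n = 3, limma adjusted p = 0.00021 and 0.0031). These were the 2 calls among 6 tested, also adjusted over the list alone, and with the block 2 were higher and 1 was lower. The camera adjusted p of the list was 0.72, 0.40 with the block, and 0.025 with the block and without both libraries numbered 3. With an estimated correlation the list had an adjusted p of 0.81, and 0.69 with the block.

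CD74 was the 1 call among 4 leukocyte and macrophage markers, also adjusted over the list alone. The camera adjusted p of this list was 0.071, 0.058 with the block, 0.031 without Dox+ 3, and 0.018 with the block and without both libraries numbered 3. With an estimated correlation this list had an adjusted p of 0.49, and 0.55 with the block. Of 3 endothelial markers, 0 passed in limma, edgeR or DESeq2, at an unadjusted p under 0.05, adjusted over the list alone or with the block (median 0.07, mean -0.21, camera adjusted p = 0.79). Of 4 adipocyte markers, 0 passed in limma and edgeR, while 2 passed in DESeq2 and at an unadjusted p under 0.05, and 2 were higher adjusted over the list alone and with the block, LPL, a lipase (1.71-fold, limma adjusted p = 0.061, and 0.031 with the block), and the adipokine gene ADIPOQ (3.42-fold, adjusted p = 0.14, and 0.014 with the block) (camera adjusted p = 0.30). Of 3 erythroid genes, 0 passed in limma and edgeR, while 1 passed in DESeq2 and at an unadjusted p under 0.05, and 1 was lower adjusted over the list alone and with the block: the haemoglobin gene HBA, at 76910 ± 26900 in Dox- and 36251 ± 13118 in Dox+ cells (n = 3, limma adjusted p = 0.20, and 0.023 with the block; camera adjusted p = 0.11). Of skeletal muscle markers only TNNT3 was tested, and of osteoblast and osteocyte markers SP7 and SOST, under the minimum of 3 for a list test. None of these 3 passed in limma, edgeR or DESeq2, at an unadjusted p under 0.05 or adjusted over the list alone, and with the block SP7, a bone transcription factor, was lower (1.81-fold, limma adjusted p = 0.74, and 0.045 with the block).

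The authors' deposited table gave 769 genes as higher and 301 as lower among 14664 with an adjusted p, at the threshold of 0.05. In the authors' deposited table, PRG4 had a log2 fold change of 8.60, CREB5 of 5.56, ACAN of -2.22 and COL2A1 of -1.40, the last with an adjusted p of 1.9e-08. For CXCL5 the authors' deposited table gave a log2 fold change of 0.15 (adjusted p = 0.026), against 5.50 in limma. With its standard error of 0.45, that fold change cannot have given the unadjusted p of 0.0016 beside it. For MX2 it gave 2.96, against 3.43 in DESeq2 with the block on the recovered reads. The table's fold changes were thus probably shrunken after the test, and the 0.15 does not mean that CXCL5 was unchanged. Of 128 named identifiers, 11 had log2 fold changes over 1 apart between limma and the authors' deposited table, among them PLPPR4 (15.34 in the table and 11.18 in limma) and CXCL8 (0.26 and 2.77). All 379 genes called here without the block, and 852 of the 858 called with it, were past the threshold in the same direction in the authors' deposited table.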

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

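Among the tests in this part, only the edgeR and DESeq2 fits with the replicate block, and the list tests by estimated correlation and fry with the block, were chosen after the result was seen. CREB5 and PRG4 kept their direction and their call under all 22 alternatives, with log2 fold changes of 5.34 to 5.84 and 8.21 to 8.99 when 1 library or 1 pair was left out. The number of genes higher, 332, was 640 with the replicate block, 542 in DESeq2, 591 in edgeR with the block and 740 in DESeq2 with the block, and the number lower, 47, was 218, 159, 190 and 308 in the same fits, 98 with library weights and 23 without the trend. With 1 library left out, 138 to 364 genes were higher and 9 to 72 lower, and with the block and 1 pair left out 576 to 961 and 186 to 538. The cause of these shifts was not tested, apart from the loss of libraries in the last. Pseudocounts, filters, TMM and quantile normalization and edgeR without the block gave 266 to 365 higher and 39 to 48 lower genes. Quantile normalization, which moved the median of all genes to -0.08, left 85.8% of calls higher.

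With the replicate block, 34 named genes passed that had not passed without it. Those not given with the results were ANGPTL7 (0.010), CD44 (0.026), COL6A2 (0.035), DES (0.0014), GDF6 (0.015), PFKFB3 (0.039), SOX4 (0.0079) and THBS4 (0.022), by limma adjusted p. The block changed no other call of a named gene and no camera call of a list. Named calls lost under a setting other than a left-out library were 15 without the trend (adjusted p from 0.0502 for MMP3 to 0.12 for MGP, with ACAN, CHAD, C1QL1, GFAP, FAT2, BMP2, CXCL5, DUSP6, FBN1, PLAU, POSTN, PPARGC1A and PTGES), 8 in edgeR (0.052 for BMP2 to 0.059 for PPARGC1A, with CXCL5, DUSP6, FAT2, INHBE, MGP and POSTN), 4 without a filter (CXCL5, FAT2, FBN1 and INHBE, up to 0.057), BMP2 and FBN1 by quantile normalization (0.055 and 0.058), FAT2 by library weights (0.053) and CXCL5 at a pseudocount of 0.5 (0.067). Over 22 alternatives the adjusted p ranged from 4.3e-49 to 0.21 for MGP and 1.0e-09 to 0.65 for COL2A1. The lowest value of COL2A1 came from the block without both libraries numbered 3, a fit with very few residual degrees of freedom per gene. Over the named genes and all alternatives, 2318 comparisons kept direction and side of the threshold, 298 passed newly, 109 no longer passed and 32 turned sign, none of the last from a call.

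Of the 12 lists that passed, 0 passed with an estimated correlation and 4 by fry. With the block 0 and 3 of them did, the synovial list being lost by fry (0.056), and the superficial zone list, not among the 12, brought the number by fry to 4 (0.039). In camera, 10 to 15 lists passed with 1 library or pair left out. Under other settings the cAMP list lost its call with library weights (0.079), the stress response list by quantile normalization (0.058) and the synovial list without a filter (0.051), while the superficial zone and joint development lists passed in edgeR (0.031 and 0.017) and, with the block, in edgeR too (0.00031 and 0.048). The leukocyte list passed at a mean of at least 50 (0.027) and in edgeR with the block (0.048).

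Signs turned only for genes and lists that had not passed in limma or camera. Quantile normalization gave log2 fold changes of -0.10 for TEK, -0.23 for VWF and -0.33 for CSF1R, library weights -0.29 for TEK and 0.13 for AHSP, and edgeR with the block 0.01 for AHSP. With libraries or pairs left out the ranges were -0.62 to 0.41 for SOX9, -0.068 to 0.58 for SC5D, -0.24 to 0.56 for TEK, -0.37 to 0.40 for VWF, -0.53 to 0.67 for CD14, -0.47 to 0.60 for CSF1R, -0.55 to 0.22 for TNNT3, -1.39 to 0.082 for FABP4 and -0.47 to 0.48 for AHSP. Lists that turned direction had these adjusted p: chondrogenic factors 0.89 without a filter and 0.78 by fry with the block; hypertrophy 0.75 in edgeR, 0.92 in edgeR with the block, 0.46 by fry and 0.54 by fry with the block; fibroblastic matrix 0.62 by quantile normalization. TGF-beta had 0.84 by quantile normalization and 0.25 by fry with the block, inflammatory genes 0.96 with library weights, 0.98 without the trend and 0.84 by fry, and cholesterol synthesis 0.76 with library weights and 0.98 in edgeR with the block. With libraries or pairs left out their adjusted p were 0.51 to 0.97 (chondrogenic factors), 0.19 to 0.95 (hypertrophy), 0.53 to 0.97 (fibroblastic matrix), 0.59 to 0.97 (tendon and ligament), 0.55 to 0.97 (AP-1 and ATF), 0.39 to 0.95 (TGF-beta), 0.19 to 0.99 (inflammatory genes), 0.10 to 0.98 (cholesterol synthesis) and 0.53 to 0.98 (endothelial). The cause was not tested for any of these. Depth limited genes near the floor, which was highest in Dox+ 3 (6.98 normalized counts).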

Other observations

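In this part, the tests of synovial fibroblasts, of doxycycline itself, of rises by the Dox- level, of the interferon list without Dox+ 3, of neighbouring paralogs and gene-poor stretches, the intervals and blocked values of the share of higher genes and of neighbouring pairs, and the counts of other splits by unadjusted p and by edgeR were chosen after the result was seen, and the other tests were written down before it. A set of 16 genes had at most 3 reads over the Dox- libraries and at least 50 normalized counts in each Dox+ library, while 0 genes went the other way. Chosen by this rule after their values were seen, and apart from TGM3, PLPPR4, CALCB, NRG1, FILIP1 and MAL2, these were the secreted ligand genes BMP3 and ADCYAP1, the chemokine gene GRO1, the secreted protease gene ADAMTS19, the peptidase inhibitor gene SPINK6, the synapse protein genes NLGN1 and NETO2, and AMTN, RANBP3L and ART3. BMP3 had 0 Dox- reads and 134, 83.9 and 181 normalized counts in Dox+ 1, 2 and 3, and ADCYAP1, which encodes the neuropeptide PACAP, had 0 and 225, 103 and 988. CCN3, a matricellular protein gene chosen after its values were seen, was 1305 ± 201 in Dox- and 152340 ± 3608 in Dox+ cells (n = 3), a 118-fold rise by limma (adjusted p = 5.9e-07).

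More genes were higher than lower with doxycycline, 332 against 47. A scaling that differs between the groups was argued against in the fit without the block. Under quantile normalization 85.8% of the called genes were higher there (95% exact interval 81.6% to 89.3%). A share of 60% or less had been set as the sign of a scaling cause and over 75% as a sign against it. Quantile normalization was not run with the block, where 74.6% of calls were higher without it. The intervals here treat genes as independent draws. Rises from low starting levels may account for part of the excess and stay open: among called genes with a Dox- mean of at least 100, 143 were higher and 46 lower, or 75.7% (interval 68.9% to 81.6%), and with the block 312 and 202, or 60.7% (56.3% to 64.9%), so that 75% lay inside the first interval and 60% inside the second. This filter acts on 1 side, since it left out 189 higher and 1 lower called genes, and 328 and 16 with the block. It thus lowers the share of higher genes whatever the cause. The share of 78.6% among called genes with a mean of at least 1000 over all libraries decides nothing, since genes that rise from near zero, such as TGM3, pass that second filter. A response of the cells to CREB5 is the explanation that the design names, and is not tested apart from these.

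By camera with the preset correlation, cartilage matrix genes were lower as a list while PRG4 was higher. Of the 16 tested members 3 were called lower and 1 higher. With an estimated correlation or by fry the list did not pass (adjusted p = 0.32 and 0.17). Synovial fibroblasts in the Dox+ cultures, which also express PRG4, were considered as a source of the cartilage fall. Their 5 tested markers had a median log2 fold change of -0.81 (camera adjusted p = 0.0070, and 0.25 with an estimated correlation), so the markers showed no gain. All had counts in the Dox- cells too, from 44.9 ± 27.0 (CD55) to 44522 ± 14910 (THY1) normalized counts (n = 3), and THY1 also stands in the fibroblastic list. A change within the chondrocytes can therefore not be told apart from a change in the share of synovial cells, and this explanation stays open. A small share of such cells could also raise PRG4, because the high baseline of markers such as THY1 would hide it. Such cells would have to supply the 0.493% to 1.05% of all Dox+ normalized counts that PRG4 held. CD55, whose baseline was the lowest, showed no gain (log2 fold change -1.67, limma adjusted p = 0.45). In limma 0 of the 5 markers were called higher, which decides nothing. Reads taken up by PRG4 and other rising genes were argued against, since the list's median stayed at -1.45 after quantile normalization, below the bound of -1. An effect of doxycycline itself cannot be told apart from that of CREB5, since 0 libraries had doxycycline without the transgene, and a response to CREB5 stays open beside it.

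A hypothesis of this re-analysis was that called genes lie next to each other on the chromosomes. Of 318 called higher genes that could be placed, 35 adjacent pairs of tested genes were both higher, against a mean of 7.73 and a 95th percentile of 12 in a permutation test of 10000 random relabellings (p = 0.0001, the smallest they can give), and with the block 85 pairs against a mean of 28.3. Reads shared between neighbouring paralogs with like symbols were argued against, since 32 pairs remained after leaving out those with shared leading letters in their symbols. Paralogs with unlike symbols or without a symbol cannot be seen by this rule, so for them the explanation stays open. Low-expressed genes that lie together in gene-poor stretches were also argued against, since relabelling within classes of level and distance gave a mean of 11.9 and a 95th percentile of 18. Shared regulation of neighbouring genes may therefore be present, as in CCN3, MAL2, TNFRSF11B and EXT1, but transcripts that run on into the next gene were not tested and stay open.

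For called lower genes, 0 adjacent pairs were found among 45 placed, against a mean of 0.15, and 1 pair was called in opposite directions. The interferon response list had a median log2 fold change of 0.43 without Dox+ 3, against 1.30 with all libraries. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one itself, gave as many as its 379 called genes and the highest other gave 0, and 10 splits are too few for a share under 0.05. Of the 4 splits that part all 3 same-numbered pairs, only 1, the real one itself, gave as many as its 858 called genes with the block, and the highest of the others, each with 1 pair exchanged, gave 0, again too few for a share under 0.05. At an unadjusted p under 0.05 the other 9 splits gave 36 to 3286 genes, against 1395 in the real one, and edgeR called 0 in each. The split with 3286 exchanged Dox- 1 and Dox+ 2, which points to a structure of the libraries beside doxycycline, and CREB5 and PRG4 stood on the labelled side in both. In the other splits with the block, 29 to 245 genes had an unadjusted p under 0.05, against 2141 in the real one, and edgeR called 0.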
